A study of Mus musculus with 3 samples.

How the data were processed

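RNA came from sorted A2.snail embryonic stem cell progeny at day 3 of differentiation as embryoid bodies in medium with serum and DKK1: untreated Flk1- cells, and Flk1- and Flk1+ cells of a culture with 250 ng/mL doxycycline from day 2. Per the labels' protocols, total RNA was isolated with a column kit and biotinylated cRNA was made from 2 ug by the standard Affymetrix procedure. The values deposited by the authors are 1 intensity per probe set and array on a linear scale, from 0.5 to about 18191 by the values themselves. The summary method, the scaling target and the software are not given in the sources used here. The columns have similar 2% trimmed means (264, 274 and 279) and are not quantile equal. There were 3 arrays, 1 for each group, which limits the precision; nothing measures the spread between cultures, and no array of doxycycline-treated cells without the Snail gene was used here, so Snail and doxycycline are not separated.

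The 45037 probe sets were named through the platform's gene annotation, with symbols updated by Entrez ID to the GRCm38.p6 RefSeq gene table. Of these, 34945 had 1 symbol, 932 several and 9160 none; only the first kind was used, and 204 of it had no match in the gene table and kept the annotation's symbol. Planned checks on Affymetrix control probe sets could not be made, because 0 of them were among the probe sets used here. Intensities were turned into log2(value + 9.53), the offset being the 20th percentile of all values, which understates differences of dim genes. The array medians on this scale (5.71, 5.70 and 5.76) lay within 0.1, so the columns were used as deposited. Each gene was represented by its probe set with the highest mean, and 13969 of 18193 genes were measured, meaning at or above the floor, the 40th percentile of all values (25.6 intensity units), on at least 1 array. Folds are 2 to the power of the log2 difference on this scale. Where the dimmer value lay under the floor, the brighter value divided by the floor is given instead, as at least that many fold, and no fold is given where both lay under it.

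The comparisons were Snail-induced Flk1- against untreated Flk1-, Snail-induced Flk1+ against Snail-induced Flk1-, and Snail-induced Flk1+ against untreated Flk1-. Genes at least 2-fold apart were counted, with no test. Named genes were, for each comparison, Snai1 and Kdr, the 10 measured genes with the largest difference in each direction whose probe sets above the floor all had 1 sign (clone and accession names skipped), and for each gene list up to 4 members with the largest difference plus up to 2 that went the other way; other genes are said to have been picked after their values were seen. The text names only part of the genes this rule takes; 1 of those with the largest differences, and 1 gene family examined after the data were seen, are not reported here. The 17 gene lists (epithelial, mesenchymal, naive pluripotency, primed epiblast, primitive streak, nascent and lateral mesoderm, endothelial and hemangioblast, hematopoietic, primitive and visceral endoderm, neural ectoderm, Wnt/beta-catenin targets, BMP/Smad targets, feeder fibroblast, cell cycle, immediate early and heat shock, p53 and apoptosis, hypoxia and glycolysis) came from textbook knowledge. Lists, rules and alternatives, except where said otherwise, were set before the data were examined. Of the 391 listed genes, 13 had no probe set of their own and were not analysed here, among them Brachyury. Each list's median log2 difference was placed among 10000 random lists of the same size drawn from the same 20 bins of mean expression, and a list is said to stand apart outside the 2.5th to 97.5th percentile; this describes these arrays and is no test of the conditions.

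The list step was tested on simulated data, the first comparison's 13969 genes with their differences shuffled within bins of mean expression. Lists of 20 genes shifted by 0.25 and 0.5 stood apart in 78% and 100% of 100 cases, and 5.5% of 200 unshifted lists did. Shuffling removes the shared regulation of real lists, so these shares hold for lists of unrelated genes. A further 200 genes were given a log2 difference of 2 in the finished gene table. That 100% of them were recovered follows by construction and checks only the counting. As a check of the measurement that needs no replicate, the differences of the brightest and the second probe set of 6493 genes were correlated across genes, which are not independent replicates (Pearson r of 0.51, 0.63 and 0.70 for the 3 comparisons). Both probe sets read the same RNA on the same array, so their agreement cannot check differences between cultures or sorts. Alternatives were quantile normalisation, centring of each array on its median over measured genes, the mean of all probe sets of a gene, leaving out probe sets with the suffix for several transcripts, no floor or a floor at the 60th percentile, no offset, a threshold of 3-fold, the mean over list members, and members in no other list; setting values under the floor to the floor was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.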

Results

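Gene expression was measured with Affymetrix arrays in sorted cells from mouse embryonic stem cells of the A2.snail line, in which doxycycline switches on Snail. Snail, encoded by Snai1, is a zinc finger repressor of epithelial genes that drives epithelial to mesenchymal transition. The cells had differentiated as embryoid bodies, floating aggregates that form early germ layer cells, in the presence of DKK1, a secreted inhibitor of Wnt signalling. At day 3 they were sorted on Flk1, the VEGF receptor encoded by Kdr, which marks mesoderm able to form endothelium and blood. There were 3 arrays, 1 per group: Flk1- cells of an untreated culture, and Flk1- and Flk1+ cells of a culture given 250 ng/mL doxycycline on day 2 (Snail-induced Flk1- and Snail-induced Flk1+ below). Each array held 45037 probe sets, with median intensities of 42.7, 42.4 and 44.6 in that order. Of 18193 genes, 13969 reached the floor of 25.6 intensity units, the 40th percentile of all values, on at least 1 array. With no replicate arrays, no difference has a replicate check and no p-value is given; the number of arrays limits the precision. Differences are therefore described by a fixed rule of size, at least 2-fold, and by the medians of 17 gene lists set against random lists.

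The induced gene and the sorted gene were read first. The single Snai1 probe set gave 29.1 in untreated Flk1-, 13.1 in Snail-induced Flk1- and 19.8 in Snail-induced Flk1+ cells, near or under the floor on every array, so it did not show the induced gene. Whether it lies within the transgene is not given in the sources used here, and it checks nothing about the doxycycline labels. The Kdr probe set gave 10.5, 9.73 and 404, at least 15.8-fold higher in the Flk1+ array than in either Flk1- array. Because the cells were sorted on its protein, Kdr checks the sort labels and is no finding.

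The first comparison asks what differed with Snail induction among cells that stayed Flk1-. Genes of epithelial junctions were lower and genes of mesenchymal cells were higher in the Snail-induced array. The tight junction genes Cldn7, Cldn6, Ocln and Marveld2 were 5.93-fold, 4.85-fold, 4.28-fold and 3.86-fold lower; Cldn7 stood at 950 in untreated and 152 in Snail-induced Flk1- cells. Crb3, a regulator of apical polarity, was 4.38-fold lower. Cdh11, a cadherin of mesenchymal cells, was 10.6-fold higher, from 53.5 to 658, and the matrix protein gene Tgfbi was 12-fold higher, from 98.3 to 1287. The collagen gene Col5a2 was at least 11.2-fold higher, reaching 285 from a level under the floor.

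Among the other genes with the largest differences, Fat4, an atypical cadherin, was 7.49-fold higher. Naalad2, Adamdec1, Pknox2, Art5, Tril and the muscle and endothelial transcription factor gene Mef2c started under the floor and were higher by at least 11.7-fold, 9.48-fold, 8.73-fold, 6.53-fold, 5.80-fold and 3.23-fold. Trh, which encodes thyrotropin-releasing hormone, was 3.69-fold lower, from 3135 to 843. Mal2, Golt1a and Tmem125 stood under the floor after induction and were lower by at least 3.33-fold, 1.56-fold and 1.38-fold. Slc9a3, a sodium and proton exchanger gene, was at least 7.82-fold lower, but its single measured probe set gave 200 in untreated, 16.9 in Snail-induced Flk1- and again 210 in Snail-induced Flk1+ cells; Golt1a likewise gave 39.97, 3.72 and 38.6.

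Of 34 measured epithelial genes, 21 were at least 2-fold lower and 0 higher, with a median log2 difference of -1.15, below all 10000 random lists. Cdh1, which encodes E-cadherin, was 2.05-fold lower, and the keratin gene Krt18 was 3.46-fold lower; both were picked after their values were seen. Of 26 mesenchymal genes, 12 were at least 2-fold higher and 0 lower (median 0.80, above all random lists). Col3a1 and Foxc1 were at least 4.77-fold and 3.53-fold higher, and Zeb1, Zeb2 and Twist1, repressors of epithelial genes also picked after their values were seen, were 3.68-fold, 3.73-fold and 3.29-fold higher; 1 of the 4 Zeb2 probe sets went the other way here and in the third comparison. Beside this, the feeder fibroblast list, which shares 4 measured genes with the mesenchymal list, had a median of 0.58 with 4 of 18 genes higher, among them Dcn at 2.37-fold and Pdgfrb at 2.64-fold. The immediate early and heat shock list, a sign of handling or signalling, had a median of 0.34 with 2 of 24 genes higher, Junb at 2.23-fold and Jun at 2.14-fold.

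Smaller differences were found in other lists. The BMP/Smad target list had a median of 0.32 with 3 of 14 genes higher, Id1 and Id4 at 2.58-fold and 2.47-fold and Gata3 with both values under the floor. The primitive and visceral endoderm list had a median of 0.28, with Pdgfra, Dab2 and Rbp4 higher at 5.72-fold, 2.32-fold and 2.30-fold and Foxa1 at least 1.82-fold lower among 19 genes. The endothelial and hemangioblast list had a median of 0.20 with 5 of 34 genes higher. Ets1 was 6.04-fold higher, Fli1, Adgrf5 and Sox18 were at least 5.76-fold, 2.07-fold and 1.18-fold higher, and Ecscr, picked after its values were seen, was 2.24-fold higher. The naive pluripotency list had a median of 0.19 with 0 of 23 genes past 2-fold; Nanog stood at 1767 and 1584. Fgf5, a gene of the primed epiblast, was 2.60-fold lower, the only one of 15 genes of its list past 2-fold. In the nascent and lateral mesoderm list, 5 of 21 genes were higher and 0 lower, led by Mef2c, Pdgfra at 5.72-fold and Isl1 at 4.10-fold, while the list median was -0.07. In the neural ectoderm list, 4 of 19 genes were higher and 0 lower, Ncam1, Zic1, Irx3 and Lhx2 at 5.70-fold, 3.69-fold, 3.29-fold and 2.89-fold, with a median of -0.14. Ptprc, a leukocyte gene, was at least 1.5-fold lower and the only one of 16 hematopoietic genes past 2-fold (median -0.22). The medians of the primitive streak (-0.02), Wnt/beta-catenin target (0.16), cell cycle (-0.03), p53 and apoptosis (0.12) and hypoxia and glycolysis (-0.04) lists lay within the range of random lists, and only the primitive streak list held genes past 2-fold, Frzb and Gsc, at least 2.91-fold and 3.60-fold higher.

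In all, 412 genes were at least 2-fold higher and 283 at least 2-fold lower, and 8 of the 17 lists stood outside the central range of random lists. Lists of unrelated genes would give 0.85, a figure that does not allow for genes regulated together, shared members or differences between cultures. Of 270 genes past 2-fold with a second measured probe set, that probe set had the same sign in 84.4%, and in 112 genes it was itself past 2-fold in that direction. Such agreement, here and below, is within the same arrays and does not stand in for a replicate. Centring each array on its median gave 314 higher and 398 lower, 44.1% of the calls higher against 59.3%, and the count of lower genes moved between 168 and 528 with the floor, the offset and the choice of probe sets. With values under the floor set to the floor, the endothelial list's median was 0 and no longer stood apart. With the mean over members in place of the median the naive pluripotency list (0.22) did not stand apart and the nascent mesoderm (0.39) and neural ectoderm (0.29) lists turned positive and stood apart, as the latter did with the floor at the 60th percentile (0.48). That mean also put the hematopoietic list apart (-0.34), as quantile normalisation did the cell cycle list (-0.080). The primed epiblast list (median -0.05) stood apart with quantile normalisation (-0.14), no floor (-0.10), the mean over members (-0.18) and members in no other list (-0.10).

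**Figure D1:**
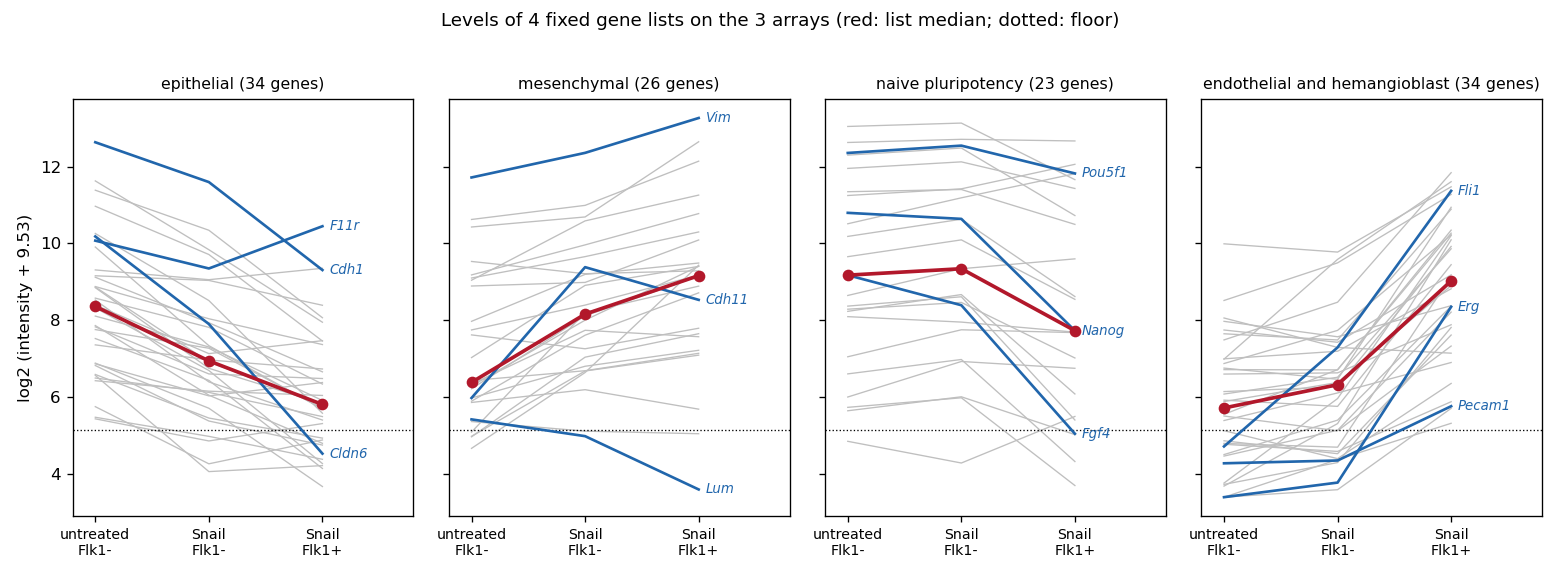
Levels of 4 gene lists on the 3 arrays, as log2 of intensity plus an offset of 9.53 on the vertical axis, with the groups on the horizontal axis. Each grey line is 1 measured gene, blue lines are the genes named beside them, the red line is the median of the levels on each array and the dotted line is the floor. From untreated Flk1- to Snail-induced Flk1+ cells, 27 of 34 epithelial genes stepped down at each array and 19 of 26 mesenchymal genes stepped up.

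The second comparison asks how Flk1+ and Flk1- cells of the Snail-induced culture differed. Without untreated Flk1+ cells it cannot say whether Snail changed Flk1+ cells. Genes of endothelial cells and their precursors were higher in the Flk1+ array, and genes of the pluripotent epiblast were lower. Of 34 measured endothelial and hemangioblast genes, 30 were at least 2-fold higher and 0 lower, with a median log2 difference of 2.74, above all 10000 random lists. Sox18, an endothelial transcription factor gene, was 27.5-fold higher, from 30.2 to 1082. Lmo2, needed for blood and vessel formation, was 22.3-fold higher, from 78.8 to 1955, and the VEGF receptor gene Flt1 and the ETS factor gene Erg were at least 21.7-fold and 12.4-fold higher.

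The BMP/Smad target list moved with it: 10 of 14 genes were higher and 0 lower (median 1.37). Its members Smad6, Bambi and Id1 were 5.97-fold, 4.83-fold and 3.93-fold higher and Gata3 at least 7.70-fold. The list shares 1 measured gene with the endothelial list, and BMP signalling itself was not measured. Of 21 nascent and lateral mesoderm genes, 8 were higher and 0 lower (median 0.61), led by the apelin receptor gene Aplnr at 24.7-fold, Rspo3 at 9.44-fold and Mef2c at 6.84-fold. In the hematopoietic list, 4 of 16 genes were higher and 1 lower (median 0.55); Lyl1 and Zfpm1 were 6.43-fold and 4.41-fold higher and Myb was 2.74-fold lower. The hematopoietic genes Gata1 (32.6 and 44.5) and Itga2b (182 and 262), picked after their values were seen, were not past 2-fold. Of 26 mesenchymal genes, 7 were higher and 1, Lum with both values under the floor, lower (median 0.63), with Foxc1 at 6.93-fold and the fibronectin gene Fn1 at 3.88-fold, while Cdh11 stood at 658 in Flk1- and 360 in Flk1+ cells, although 1 of its 2 probe sets was slightly higher. The feeder fibroblast list did not stand apart (median -0.07), and its gene Dcn was 4.19-fold lower. The immediate early list did not either (median 0.12), although Atf3 and Jun were 8.09-fold and 2.26-fold higher and Egr1 and Hspb1 were 2.90-fold and 2.49-fold lower.

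Epithelial genes were lower again: 16 of 34 were at least 2-fold lower and 1 higher (median -0.96). Cldn6 was at least 8.98-fold lower and Esrp1, a splicing factor gene of epithelial cells, was 7.63-fold lower, while F11r, a junction gene that endothelium also expresses, was 2.14-fold higher. Of 23 naive pluripotency genes, 11 were lower and 1 higher (median -0.98). Nanog was 7.51-fold lower, from 1584 to 203, Nr0b1 was 9.24-fold lower, and Fgf4 and Tfcp2l1 were at least 12.8-fold and 4.56-fold lower; 1 of the 3 measured Fgf4 probe sets went the other way. Pou5f1, the core pluripotency gene, picked after its values were seen, stood at 5963 and 3607. Of 15 primed epiblast genes, 7 were lower and 0 higher (median -0.91), with Fgf5, Foxd3 and Zic5 at 6.55-fold, 6.09-fold and 4.08-fold. The primitive and visceral endoderm list went both ways, 5 of 19 higher and 2 lower (median 0.13): Sox17, also an endothelial gene, and the basement membrane genes Col4a2 and Col4a1 were 14.0-fold, 5.17-fold and 5.02-fold higher, and Cubn and Rhox5 were 4.99-fold and 3.69-fold lower. In the primitive streak list, 2 of 11 genes were higher and 4 lower (median 0.12), with Fst 4.38-fold lower. The Wnt/beta-catenin target list did not stand apart (median -0.03): Lgr5 and Dkk1 were 4.86-fold and 3.55-fold higher and Sp8 was 2.49-fold lower. The neural ectoderm (-0.04), cell cycle (-0.05), p53 and apoptosis (-0.07) and hypoxia and glycolysis (-0.10) lists did not stand apart either; 0 of 23 cell cycle genes were past 2-fold, while Pmaip1, a pro-apoptotic p53 target, was 3.83-fold lower.

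The largest differences by gene were those of Ctla2a and Ctla2b, at least 113-fold and 63.7-fold higher, but these paralogs are near-identical in sequence and their probe sets may read each other, so the level of each is uncertain. Hapln1, which links hyaluronan to the matrix, Car8 and Myct1 were at least 42.7-fold, 38.8-fold and 30.3-fold higher, and Myzap and Tnfaip2 were 38.8-fold and 24.6-fold higher. Eras, a Ras gene of embryonic stem cells, was 17.3-fold lower, from 829 to 39.0, Fbxo15, another gene of those cells, was 10.1-fold lower, and Crabp2, a retinoic acid binding protein gene, and Trh were 8.56-fold and 8.48-fold lower. Mcf2 and Mymx were 8.71-fold and 8.37-fold lower, and Pycard and Morc1 were at least 9.37-fold and 7.22-fold lower. In all, 678 genes were at least 2-fold higher and 683 lower, and 8 of the 17 lists stood apart. Of 531 genes past 2-fold with a second probe set, 90.6% had the same sign there, and 283 were past 2-fold there in that direction. With the floor at the 60th percentile the primitive streak list turned to -0.91 over the 7 genes left and stood apart, and with the mean over all probe sets of a gene the neural ectoderm list (-0.29) stood apart.

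**Figure D2:**
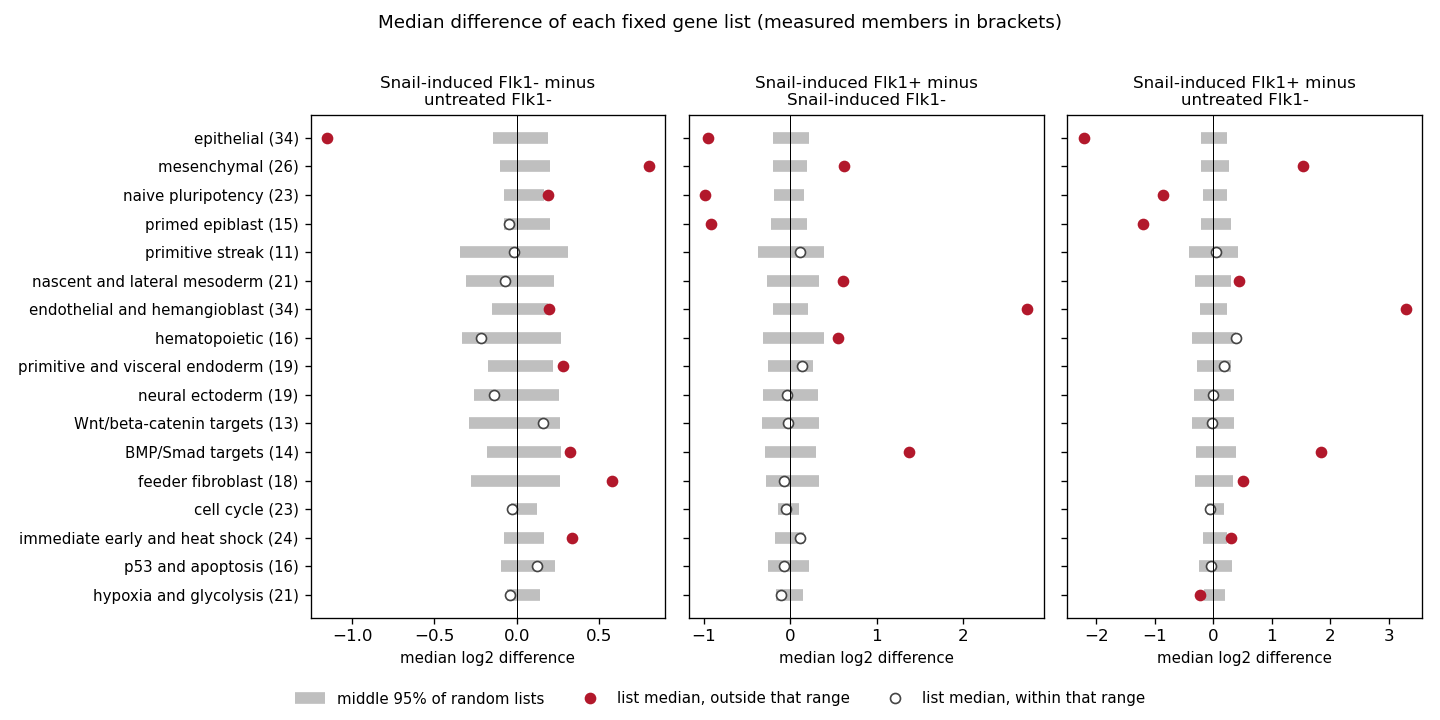
Median log2 difference of each of the 17 gene lists in the 3 comparisons, with the lists on the vertical axis and the difference on the horizontal axis, whose scale differs between panels. Grey bars span random lists of the same size and expression, leaving out 2.5% at each end, filled points lie outside that span and open points inside it. The endothelial and hemangioblast list reaches 2.74 in Snail-induced Flk1+ against Flk1- cells, and the epithelial list lies left of the random span in each comparison.

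The third comparison, Snail-induced Flk1+ against untreated Flk1- cells, is on the log scale the sum of the other two and gives no independent evidence. It joins induction with the Flk1 gate. No array of untreated Flk1+ cells was used here, so its differences cannot be put down to Snail alone. Epithelial genes were lowest and endothelial genes highest here. Of 34 epithelial genes, 25 were at least 2-fold lower and 0 higher (median -2.22), with Cldn6 at least 45-fold lower and Esrp1 and Cldn7 at 25.6-fold and 18.6-fold; Krt8 (625 and 644) and F11r (1067 and 1386) were the measured members that were not lower, and Krt8 turns slightly lower with quantile normalisation or centring. Of 26 mesenchymal genes, 20 were higher and 1 lower (median 1.53), with Foxc1 and Col5a2 at least 26.7-fold and 18.2-fold and Tgfb1i1 and Zeb2 8.68-fold and 7.62-fold higher and Lum at least 1.30-fold lower. Of 34 endothelial genes, 32 were higher and 0 lower (median 3.30), with Fli1, Adgrf5 and Sox18 at least 103-fold, 45.8-fold and 42.3-fold; Mmrn2 was 1.89-fold lower by its brightest probe set and turns higher (1.61 on the log2 scale) without probe sets that can read several transcripts. Calcrl, a receptor for adrenomedullin, Hapln1, Aplnr and Car8 were at least 49.9-fold, 42.7-fold, 38.8-fold and 38.8-fold higher. Eras and Trh were each 31.3-fold lower, Pard6b, a polarity gene, and Grb7 each 18.2-fold lower, Erbb3 and Ripk4 each at least 19.9-fold lower, and Mapk13 at least 10.5-fold lower.

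The other list medians followed: BMP/Smad targets 1.85 with 9 of 14 genes higher (Id1 at 10.2-fold), nascent and lateral mesoderm 0.44 with 9 of 21 higher and 1 lower (Isl1 at 12.4-fold, Dll3 at 2.41-fold lower), naive pluripotency -0.85 with 11 of 23 lower and 1 higher (Dppa2 at 2.47-fold), and primed epiblast -1.20 with 9 of 15 lower (Fgf5 at 17.0-fold). The feeder fibroblast list stood apart at 0.51, with 5 of 18 genes higher and 1 lower, and the immediate early list at 0.31, with 5 of 24 higher, Atf3 at 7.25-fold and Jun at 4.85-fold. The hypoxia and glycolysis list stood slightly below random lists at -0.22, with 4 of 21 genes higher and 4 lower; the glucose transporter genes Slc2a1 and Slc2a3 were 3.06-fold and 2.39-fold lower and Egln3 and Vegfa 2.84-fold and 2.35-fold higher. This was lost with the mean over all probe sets (-0.076) or over members (-0.16), and the feeder list with the mean over members (0.40) or without the genes it shares (0.39). The hematopoietic median of 0.39 lay at the edge of the random range and passed it under 5 other settings. The primitive and visceral endoderm median was 0.18, with 9 of 19 genes higher and 4 lower, and did not stand apart. It did with the floor at the 60th percentile (0.67) and with the mean over members (0.62). The primitive streak (0.05), neural ectoderm (0.00), Wnt/beta-catenin target (-0.01), cell cycle (-0.06) and p53 and apoptosis (-0.04) medians did not stand apart. The primitive streak median turns negative with quantile normalisation or centring, and stands apart at -0.61 over 7 genes with the floor at the 60th percentile. In all, 1132 genes were at least 2-fold higher and 896 lower (1007 and 1025 with quantile normalisation, 1030 and 1010 with centring), and 10 of the 17 lists stood apart. Of 894 genes past 2-fold with a second probe set, 93.7% had the same sign there, and 510 were past 2-fold there in that direction.

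The steps from untreated Flk1- to Snail-induced Flk1- and on to Snail-induced Flk1+ cells shared genes. Of the 412 genes higher at the first step, 106 were at least 2-fold higher again at the second and 33 lower, where independent lists would share about 20 each way. Of the 283 genes lower at the first step, 87 were lower again and 61 higher, where independent lists would share 13.8 and 13.7. Both steps use the Snail-induced Flk1- array, whose own error pushes them in opposite directions. Without replicates that error cannot be simulated, so part of the reversals may come from it. Carried-over Flk1+ cells in that array, weighed below, would move genes the same way at both steps and may add to the shared genes. The figures for independent lists also treat all measured genes as equally likely to pass 2-fold. In the epithelial list 79.4% of genes stepped down at each array, against 22.0% of all measured genes, and in the mesenchymal list 73.1% stepped up, against 27.0%.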

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

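No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. Signal over background limits the dim genes: about 59.4% to 60.7% of probe sets reached the floor on each array. Of the alternative values, 43 of 54 gene counts stayed within 1.5 times, 485 of 510 list medians and 2641 of 2718 differences of named genes stayed on their side of the threshold, of which 25 and 20, past it under neither setting, changed sign; 29 gene differences passed 2-fold, 45 dropped below it and 3 reversed. Setting values under the floor to the floor was chosen after seeing the data. At 3-fold the counts were 115 higher and 32 lower, 241 and 228, and 513 and 396 in the 3 comparisons, by the threshold's construction; the cause of the shifts below was not tested. In the first comparison, the mean of all probe sets gave 263 higher and 178 lower, and the count of lower genes was 168 with the floor at the 60th percentile, 528 with no offset and 184 with values set to the floor. There the primed epiblast list stood apart with quantile normalisation (-0.14), no floor (-0.10), the mean over members (-0.18) and members in no other list (-0.10), the cell cycle list with quantile normalisation (-0.080) and the hematopoietic list with the mean (-0.34). The mean turned the nascent mesoderm (0.39) and neural ectoderm (0.29) lists positive and apart, as the floor at the 60th percentile did the latter (0.48), and took the naive pluripotency list (0.22) inside the random range, as values set to the floor did the endothelial list (0). In the second comparison, the mean of all probe sets put the neural ectoderm list apart (-0.29), and the floor at the 60th percentile turned the primitive streak list, then apart (-0.91). In the third comparison, that floor turned it too, then apart (-0.61), and put the primitive and visceral endoderm list apart (0.67), as did the mean over members (0.62). The hematopoietic list stood apart there with quantile normalisation (0.35), without probe sets for several transcripts (0.39), with no floor (0.36), no offset (0.49) and values set to the floor (0.34). The feeder list dropped out with the mean (0.40) and without shared members (0.39), and the hypoxia list with the mean of probe sets (-0.076) or members (-0.16). Mmrn2 reversed without probe sets for several transcripts (1.55 and 1.61 in the second comparison and the third) and Lgr5 with no offset (-0.27 in the third comparison).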

Other observations

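The gene families of the next paragraph, and the tests of carry-over, were chosen after the results were seen; the other tests were set before the values they rest on.

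Some FGF ligand genes were lower in Snail-induced Flk1+ than in Snail-induced Flk1- cells. Fgf4 and Fgf5 gave 326 and 785 in Flk1- and 23.5 and 112 in Flk1+ cells; both are in the fixed lists, as is Fgf8, so their differences restate those lists. The other 9 measured ligands had a median log2 difference of -0.07, inside the random range, with 4 lower, of which Fgf11 had both values under the floor, and 1 higher. Among them Fgf15, a gene of early neural tissue and gut, gave 805 and 167. The 73 genes of mitochondrial ribosomal proteins had slightly negative medians of -0.09, -0.28 and -0.34 in the 3 comparisons, each below all random lists. Just 1 of them was past 2-fold, in the third. Not all were lower: Mrpl17 and Mrps16 differed by 0.22 and 0.25 in the first comparison and Mrps6 by 0.25 in the third. Most of the 40 cytosolic ribosomal protein genes were far brighter, so that a shift may be compressed. Others were not, such as Rps27 and Rpl12 at 111 and 756 in untreated Flk1- cells. The 40 genes stayed inside the random range (0.03, -0.06 and -0.02), which sets no contrast. Of these, only Rpl39l was past 2-fold, at 4.86-fold and 3.12-fold lower in Snail-induced Flk1+ than in Snail-induced Flk1- and untreated Flk1- cells. Among 22 imprinted genes, 9 were at least 2-fold higher and 3 lower in Snail-induced Flk1+ than in untreated Flk1- cells (median 0.48). In Snail-induced Flk1- against untreated cells 5 were higher and 0 lower (median 0.23), while between Flk1+ and Flk1- cells of the induced culture 5 were higher and 4 lower (median 0.19), inside the random range; without Dcn and Ascl2, which are in the fixed lists, the 3 medians were 0.23, 0.41 and 0.67, all above the random range. Igf2, a fetal growth factor gene, stood at 121, 449 and 3620 in untreated Flk1-, Snail-induced Flk1- and Snail-induced Flk1+ cells by its brightest probe set, while another was slightly lower in Snail-induced Flk1- than in untreated cells. Peg3 stood at 712, 1601 and 2633 and Grb10 at 2378, 4351 and 8770, while Mest and Phlda2 gave 83.0 and 232 in Flk1+ against 249 and 743 in untreated cells. The medians of the 7 claudin genes in no fixed list and of 25 semaphorin and plexin genes stayed inside the random range in all 3 comparisons (-0.16, 0.35 and 0.14, and -0.16, 0.10 and 0.10). The 25 include Plxnd1 of the endothelial list. In the third comparison 5 of the 25 were at least 2-fold higher and 3 lower. Sema6d stood at 23.2, 181 and 1187 and Sema4d at 490, 207 and 67.4 in untreated Flk1-, Snail-induced Flk1- and Snail-induced Flk1+ cells.

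In the Snail-induced Flk1- array 5 of 34 endothelial genes were at least 2-fold above their untreated level, although these cells were sorted against Flk1 and the list median was 0 with values set to the floor: Fli1 stood at 16.8 in untreated, 147 in Snail-induced Flk1- and 2632 in Flk1+ cells, and Ets1 at 117, 758 and 3106. A few carried-over Flk1+ cells would bring every abundant Flk1+ transcript in one ratio, so 63 other genes bright in Flk1+ cells (at least 500, and at least 8-fold over untreated) were set against the lowest share that the probe sets of each gene need. Kdr (10.5, 9.73 and 404), the sorted gene, fell short of 500 and was not among them. It was no higher in the Snail-induced than in the untreated Flk1- array, with both values under the floor. Levels were compared with the offset of 9.53 added, taking the untreated level as the cells' own. For Ets1 (8.23%, the lowest of 4 probe sets) 14 of the 63 lay at or under 50% of the predicted level. The shares of the 63 were spread, with a median of 8.90% and 12 under 1%. Some of the 14 lay under the floor, but Esam (44.6) and Lmo2 (78.8) did not. These values argue against carry-over as the only source for Ets1. For Ecscr (4.92%, 1 probe set) 7 of the 63 did. Among them Ctla2a, Ctla2b, Car8, Flt1 and Hapln1 lay under the floor in the Snail-induced Flk1- array, while Lmo2 (78.8) and Myzap (31.7) lay above it. The 7 passed the limit of 5 genes set for these tests after the results were seen, as the 14 for Ets1 did. For Fli1 (1.53%), Sox18 (2.49%, 1 probe set) and Adgrf5 (2.15%) 2 of the 63 lay at or under 50% in each case, the near-identical Ctla2a and Ctla2b. The brightest probe sets of Fli1 and Adgrf5 need 4.99% and 4.18%, for which 7 and 5 did, so the probe sets of these 2 genes differ. At such low shares the predicted level of many of the 63 lies close to the untreated one. Few genes could then fall to 50% of it, so a low count says little. Carry-over cannot be told apart from expression in the Flk1- cells themselves for Fli1, Sox18 and Adgrf5. For Ecscr the count went against carry-over as the only source. Most of its 7 genes lay under the floor and it has 1 probe set, so the question is left open for it too. Cells on their way to Flk1 expression are a biological candidate that stays open and untested.

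Hprt, a housekeeping gene on chromosome X, stood at 352, 2301 and 1328: 6.40-fold higher in Snail-induced Flk1- (rank 13 by size among the 412 genes at least 2-fold higher) and 3.70-fold higher in Flk1+ than in untreated cells. The 10 nearest measured genes had a median log2 difference of 0.25 (bootstrap range -0.18 to 0.67, leaving out 2.5% at each end). Single genes ran from -0.37 for Ccdc160 to 0.89 for Gpc4 and 1.14 for 1700013H16Rik. This argues against a change shared by the region in Flk1- cells, but a median cannot see one limited to a few neighbours. Between Flk1+ and untreated cells the median was 0.45 (-0.67 to 1.18), which does not exclude a change of the region. There Plac1, Phf6 and Gpc3 were higher by 1.49, 1.43 and 1.11 and Ccdc160 and 1700013H16Rik lower (-1.96 and -1.60). A fault of the untreated array or of the probe set stays open, because 0 other probe sets measure Hprt. A hypothesis is transcription from the inducible cassette: in lines of the A2lox type such a cassette lies beside Hprt, but the labels do not say where it lies in A2.snail, and this was not tested.

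Of the 695 genes past 2-fold in the first comparison, 137 (54 higher and 83 lower) were back within 0.5 log2 of the untreated level, or beyond it, in the Snail-induced Flk1+ array, as Slc9a3 was. A probe set fault on 1 array is a candidate explanation: Rbm15b gave 969, 55.7 and 1036 by its brightest probe set and 176, 200 and 242 by another, but the remaining probe set, near the floor, gave 30.7, 10.9 and 34.5 and so moved as the brightest did, and both probe sets of Slc40a1 were lower in the Flk1- array (234, 60.8 and 280, and 76.9, 29.8 and 81.7). Over the 30 such genes with a second probe set, it moved by a median of 0.27 in the same direction. For the 213 genes still at least 2-fold off the same way between Flk1+ and untreated cells the median was 0.90. Both sets were picked by their level in the Flk1+ array, which by itself may lower the ratio of these medians. The ratio of 0.30 has a bootstrap range, made the same way, of 0.03 to 1.05, so faulty probe sets and real differences of the Flk1- cells cannot be told apart for these genes as a set, which are too few.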
